A study of Mus musculus with 3 samples.

How the data were processed

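Single-cell suspensions were made from pancreatic tumours of KPC mice and of KPC mice labelled Ccr1-/-, taken when the tumours could be felt. Per the labels' protocols, the minced tissue was digested with collagenase V at 1 mg/mL for 30 min at 37 °C, passed through meshes of 500, 100 and 40 µm, depleted of dead cells with a magnetic kit and sequenced on an Illumina NovaSeq in a 50-cycle paired-end run, with a stated depth of 100000 reads. Per the labels, the KPC library was run in May 2024, library 1 labelled Ccr1-/- in February 2024 and library 2 in December 2024, with 1 mouse in each. No cell sort or gate is named. Digestion time, mesh size and dead cell removal can each set how many fibroblast, acinar, epithelial and immune cells are recovered.

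The deposited values are UMI counts per gene and barcode, and the authors made them with Cell Ranger 8.0.0 (9.0.0 for library 2 labelled Ccr1-/-) on the reference GRCm39-2024-A, per the labels. Both matrices hold whole numbers and no barcode under 500 UMIs. Counts were used as deposited, with no normalization by the authors. Of library 2 labelled Ccr1-/- only the number of barcodes was used, and its matrix was not analysed here. The coordinates of Ccr1 are those of the GRCm39 annotation used here.

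Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept, which removed 720 KPC barcodes and 629 of the library labelled Ccr1-/-. Doublets were then scored in each library against simulated doublets with an automatic threshold, following Scrublet's method (own implementation, 2 simulated doublets per cell, 0.8% expected per 1000 cells), and 418 KPC cells (3.31%, expected 10.1%) and 119 cells of the other library (1.56%, expected 6.10%) were removed. The 12210 and 7512 kept cells had medians of 3539 and 2715 UMIs. Log-normalized counts (per 10000) of 2000 variable genes chosen within libraries gave 30 principal components and a graph of 20 nearest neighbours, and Leiden clustering at resolution 1 over both libraries, without batch integration, gave 30 clusters (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2).

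Each cluster was named X-like from marker genes when at least 3 of its 20 leading genes by fold were markers of a class, no other class had 3 there or as many among the first 10, and at least 3 markers were detected in 20% of its cells. A cluster far below the median depth with no marker among its first 10 genes would also have stayed unnamed. Genes were ranked with 50 CPM added and had to be found in 20% of the cluster's cells. Doublets left after the calls and free RNA can add markers of another class to a cluster. With 1 library per genotype analysed, a cluster mostly of 1 library may be that library rather than a cell type. Clusters 15, 22, 23 and 27 stayed unnamed.

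Counts were summed per library and class and divided by the class total to give CPM. The differences in log2 CPM, library labelled Ccr1-/- minus KPC, used 10 CPM added to each level, which shrinks differences of low genes. Levels have exact Poisson intervals, ratios of levels exact intervals conditional on the total count, and shares of cells exact Clopper-Pearson intervals, all at 95%. Such intervals cover counting error only and hold nothing of the variation between mice. With 1 library with a matrix per genotype there was no test, and no p-value or count of changed genes was computed. Free RNA adds UMIs of abundant genes to all cells, so shares of cells with Ccr1 stand beside those of B/plasma-like cells, and shares were also given with each cell thinned to 1000 UMIs and shallower cells left out.

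The 33 gene lists were fixed before the data were examined, as were the markers, the filters, the rule for named genes and the first set of alternatives. They are 11 lists in macrophage/monocyte-like cells (suppressive, complement and lipid, MHC class II, MHC class I, interferon response, inflammatory cytokine, CCR1 ligand, myeloid chemokine receptor, monocyte, arginine and polyamine, glycolysis and hypoxia), 4 in T/NK-like cells (cytotoxicity, exhaustion, naive and memory, regulatory), 4 in fibroblast-like cells (myofibroblast, inflammatory, antigen presenting, collagen and matrix), 5 in epithelial-like cells (classical, basal, mesenchymal, chemokine, MHC class I), 2 each in neutrophil-like (activation, maturity) and endothelial-like cells (angiogenic, adhesion), and 5 for every class (proliferation, dissociation stress, RNA quality, ambient acinar, sex). Members at 10 CPM or more in either library count as measured. A list is described by its members on each side, the median log2 ratio, an interval from 1000 Poisson redraws of the counts, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and tests nothing.

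Named genes followed a rule of size: Ccr1, the 2 highest and 2 lowest members of each list among those at 20 CPM or more in either library, and across all genes the 10 highest and 10 lowest ratios in macrophage/monocyte-like cells and the 5 and 5 in other classes with 200 or more cells in each library. The last part took genes at 50 CPM or more in one library whose class level there was at least the level over all kept cells, and left out mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, Xist, Y-linked and unnamed gene models. Endothelial-like cells were too few for it.

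The interval and list functions were tested on simulated Poisson counts with the real totals and gene means averaged over both libraries, with 50 genes at each of the folds 0.25, 0.5, 2 and 4. Cluster mix, a shift of all genes, and variation between cells or mice were not simulated. The check is therefore of the functions and not of these data. In macrophage/monocyte-like cells the intervals held the true ratio for 95.5% of 8187 unchanged genes and for 98.0%, 98.0%, 96.0% and 100% of the changed genes in the order of the folds, and in T/NK-like cells for 95.6% of 8176 and for 96.0%, 96.0%, 98.0% and 96.0%. Lists of 20 genes at folds 0.5 and 2 reached percentiles 0.0 and 100 in both classes. A list of 20 unchanged genes reached 73.9 in macrophage/monocyte-like and 17.6 in T/NK-like cells.

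Alternatives for shares were keeping doublet calls, filters of 500 genes and 10% mitochondrial UMIs, no filter, resolutions 0.5 and 2, clustering each library on its own, and naming each cell from its own markers. Those for levels were TMM scaling (edgeR 4.0.16, R 4.3.3), median-of-ratios scaling, 1 CPM added, no minimum for members, the mean over cells, thinned cells, kept doublets, separate clustering, and subtraction of free RNA. For the last, the profile of all kept cells of a library stood for its free RNA and was scaled so that the UMIs of 92 acinar and B/plasma markers in the class were accounted for (44 acinar markers for B/plasma-like cells), and was subtracted with a floor of 0, which estimated 3.89% free RNA in macrophage/monocyte-like cells of KPC and 14.5% in the library labelled Ccr1-/-. Such scaling also counts acinar or B/plasma RNA from leftover doublets as free RNA. The number of cells expected to hold Xist from free RNA took the Xist UMIs as Poisson counts in proportion to each cell's UMIs. For 3 or more UMIs in acinar-like cells, the rate was the one at which free RNA alone gives the observed number of cells with a UMI. Leaving out a replicate could not be run. Other denominators, single clusters and totals without acinar markers were chosen after seeing the data.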

Results

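Pancreatic tumours of aged KPC mice, which carry an oncogenic Kras allele and a mutant Trp53 allele and develop pancreatic cancer, were profiled by droplet single-cell RNA sequencing, beside tumours of KPC mice labelled as lacking Ccr1. Ccr1 encodes a receptor for inflammatory chemokines such as CCL3, CCL5 and CCL7 on monocytes, macrophages and neutrophils, and the series asks what the receptor does as the cancer progresses and in tumour macrophages. The labels list 1 KPC library and 2 libraries labelled Ccr1-/-, each from 1 mouse. Count matrices of the KPC library and of library 1 labelled Ccr1-/- were used, and the matrix of library 2 labelled Ccr1-/-, with 14913 barcodes, was not analysed here. The KPC matrix held 84174827 unique molecular identifiers (UMIs) in 13348 barcodes, with a median of 3484 per barcode, and the other matrix held 41798740 UMIs in 8260 barcodes, with a median of 2600.5. After filtering, 12210 KPC cells and 7512 cells of the library labelled Ccr1-/- remained. With only 1 library per genotype analysed, no test was made and no difference has a replicate check. Genotype, mouse, library and run month were the same split, so each comparison is of 2 libraries. All intervals are 95% intervals that cover counting error only, and ratios are the level in the library labelled Ccr1-/- over the level in the KPC library.

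Ccr1, the gene named in the genotype, was found in both libraries. Ccr1 (ENSMUSG00000025804) lies on chromosome 9 of GRCm39 from 123762161 to 123768734 on the minus strand, with exon 1 (123768332 to 123768734) in the 5' untranslated region and the whole coding sequence (123763464 to 123764528) in exon 2 (123762161 to 123764595). Macrophage/monocyte-like cells held Ccr1 at 154.6 CPM (UMI counts scaled to the class total; 145 to 165) in the KPC library and 73.2 CPM (63.8 to 83.5) in the library labelled Ccr1-/-, a ratio of 0.473 (0.407 to 0.549). Neutrophil-like cells held 471.7 CPM (440.2 to 505) and 296.2 CPM (254 to 344), a ratio of 0.628 (0.530 to 0.740). Over all kept cells there were 2001 and 489 Ccr1 UMIs, or 25.0 and 12.3 CPM.

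Cells with at least 1 Ccr1 UMI made up 46.9% of macrophage/monocyte-like cells in the KPC library and 15.4% in the library labelled Ccr1-/-, at median depths of 5958 and 1788 UMIs. Thinned to 1000 UMIs per cell, with 861 of 965 and 808 of 1041 cells deep enough, the shares were 14.1% (11.8 to 16.6) and 6.19% (4.63 to 8.08). In neutrophil-like cells the unthinned shares were 58.8% and 36.7%, and the thinned shares were 37.7% (33.7 to 41.9; 554 of 640 cells) and 21.1% (16.3 to 26.5; 266 of 294 cells). B/plasma-like cells, which should lack Ccr1, gave 0.574% and 0.351% at median depths of 2638.5 and 2019 UMIs, and 1.75 and 1.43 CPM. Dendritic-like cells held 28.9 and 44.5 CPM, a ratio of 1.54 (1.08 to 2.19), but cluster 13, with 155 of the 348 and 191 of the 262 cells, held 78 of the 83 and all 55 of the UMIs, and within it the ratio was 0.997 (0.693 to 1.43). T/NK-like cells held 3.31 and 0.557 CPM, a ratio of 0.168 (0.0199 to 0.634), but cluster 2, named regulatory T-like, held 53 of the KPC UMIs, at 14.5 and 0.999 CPM (0.0689, 0.0017 to 0.401), and clusters 3, 4 and 7 held 0.204 to 0.825 CPM in KPC. Fibroblast-like cells held 1.01 and 0.659 CPM and epithelial-like cells 0.631 and 1.24 CPM. Because Ccr1 UMIs remained in the myeloid cells, the library is called labelled Ccr1-/- throughout. A 3' tag outside the deleted part of the gene checks nothing, and the labels do not say which part was deleted.

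**Figure D1:**
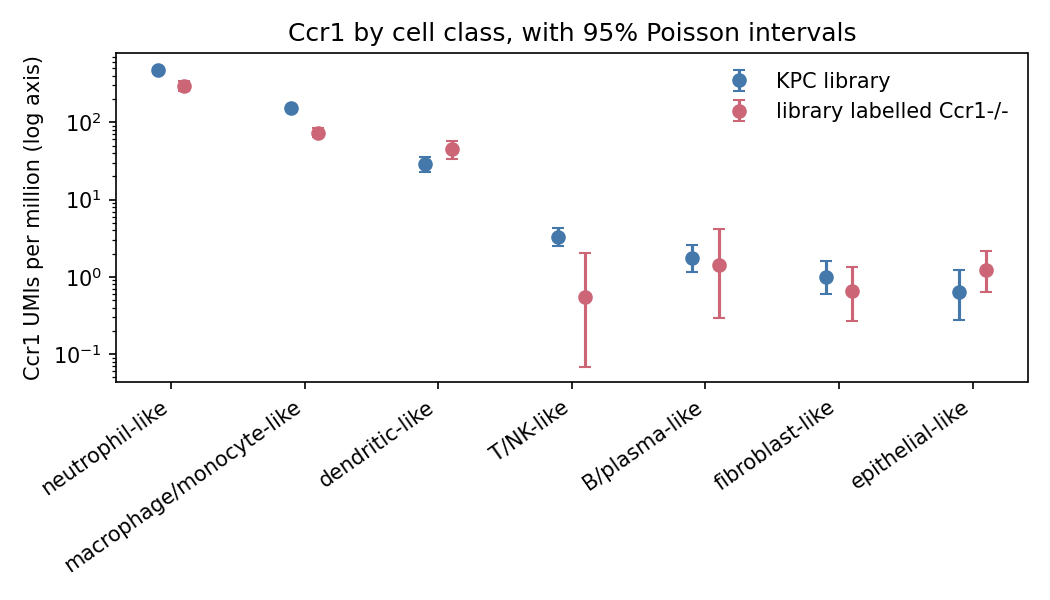
Ccr1 level in CPM (log axis) in each cell class of the KPC library (blue) and the library labelled Ccr1-/- (red), with 95% Poisson intervals. Neutrophil-like cells led in both libraries at 471.7 and 296.2 CPM, followed by macrophage/monocyte-like cells at 154.6 and 73.2 CPM.

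The cell classes differed widely between the libraries. Acinar-like cells (301), cluster 20 with genes of duct cells (197) and cluster 23 with genes of fat cells (78) held 0 KPC cells. B/plasma-like cluster 0 (3348 and 463 cells) and the Lef1-led T/NK-like clusters 3 (1095 and 103) and 7 (994 and 91) were mostly KPC. How much tissue outside the tumour each sample held was not measured. The differences below, in shares and within classes, therefore cannot be told apart from a difference in the tissue taken. T/NK-like cells made up 37.5% (36.6 to 38.4; 4578 cells) of the KPC library and 18.2% (17.3 to 19.1; 1367 cells) of the library labelled Ccr1-/-. B/plasma-like cells made up 31.4% (30.5 to 32.2) and 7.59% (6.999 to 8.21). Fibroblast-like cells were the reverse, at 9.22% (8.71 to 9.75; 1126 cells) and 36.1% (35.04 to 37.2; 2714 cells). Macrophage/monocyte-like cells made up 7.90% (7.43 to 8.40; 965 cells) and 13.9% (13.1 to 14.7; 1041 cells), and neutrophil-like cells 5.24% (4.85 to 5.65; 640 cells) and 3.91% (3.49 to 4.38; 294 cells).

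Epithelial-like cells were 3.39% (3.08 to 3.73; 414 cells) of the KPC library and 7.67% (7.08 to 8.29; 576 cells) of the library labelled Ccr1-/-. Dendritic-like cells were 2.85% and 3.49%, endothelial-like cells 0.467% and 1.93%, and mast/basophil-like cells 0.0491% and 0.386%. Acinar-like cells, the digestive enzyme producing cells of normal pancreas, were 4.01% (301 cells) of the library labelled Ccr1-/- and 0 of 12210 KPC cells, a count that allows a share of up to 0.0302% (exact binomial). With each cell named from its own markers they were 12.1% (11.4 to 12.9; 910 cells) and again 0 KPC cells. Under that naming T/NK-like cells of the library labelled Ccr1-/- numbered 910 in place of 1367 and fibroblast-like cells 2189 in place of 2714, and acinar genes were higher in every class compared of that library, so the 12.1% can include other cells that carry free acinar RNA. Clusters left unnamed held 2.01% and 2.84% of cells. The order of 3 named classes depended on the denominator: of the cells that were neither T/NK-like nor B/plasma-like, macrophage/monocyte-like cells were 25.4% (24.0 to 26.8) in the KPC library and 18.7% (17.7 to 19.7) in the library labelled Ccr1-/-, epithelial-like cells 10.9% (9.92 to 11.9) and 10.3% (9.54 to 11.2), and dendritic-like cells 9.15% (8.25 to 10.1) and 4.70% (4.16 to 5.29). On that base neutrophil-like cells were 16.8% and 5.27% and fibroblast-like cells 29.6% and 48.7%. Without clusters 0, 3 and 7 and the acinar-like cells the differences were 1.64 points for macrophage/monocyte-like and -4.96 points for neutrophil-like cells, against 5.95 and -1.33 over all kept cells, and dendritic-like cells were 5.14% and 3.998%. Both denominators were chosen after seeing the data. The epithelial-like difference of 4.28 points was 1.59 with no cell filter, 1.61 with each library clustered on its own and 1.65 with cluster 10 alone, the last also chosen after seeing the data. The fibroblast-like difference of 26.9 points was 15.9 with each library clustered on its own. That setting left 1042 cells (13.9%) of the library labelled Ccr1-/- and 0 KPC cells unnamed. The macrophage/monocyte-like difference was 3.93 with each cell named from its own markers.

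**Figure D2:**
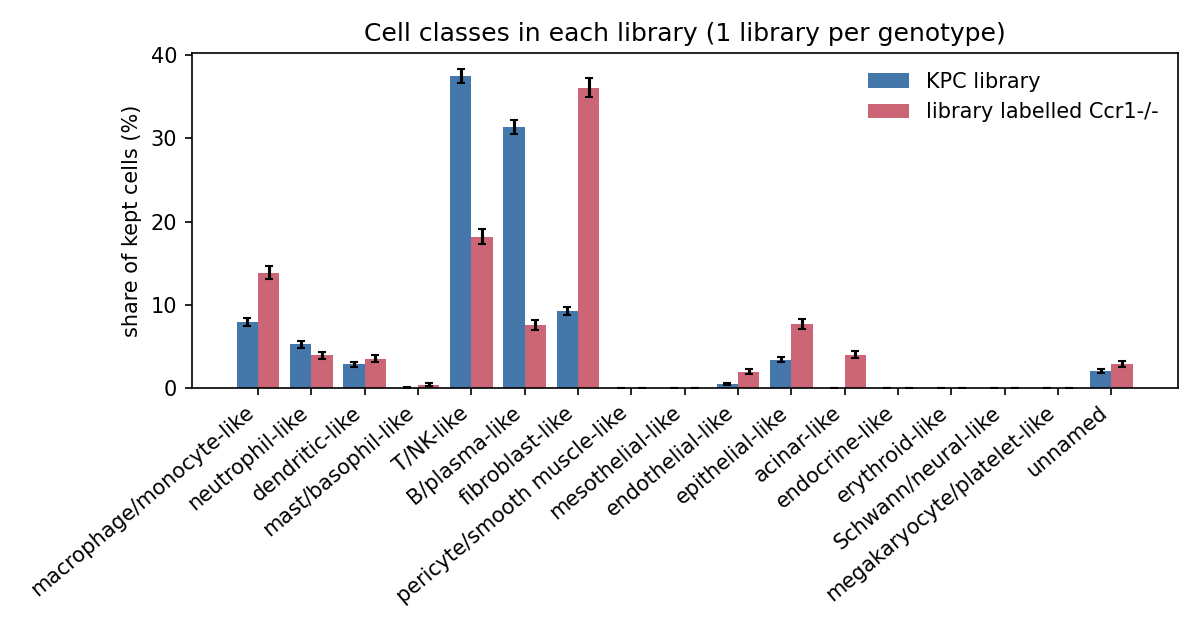
Share of kept cells (percent) in each cell class of the KPC library (blue bars) and the library labelled Ccr1-/- (red bars), with exact 95% binomial intervals. T/NK-like cells reach 37.5% and 18.2%, and fibroblast-like cells 9.22% and 36.1%.

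Macrophage/monocyte-like cells were compared to ask which programmes differed with the Ccr1 label in the cells that carry the receptor. In the library labelled Ccr1-/-, monocyte, inflammatory cytokine, hypoxia and interferon response genes were lower, and 17 of the 23 measured suppressive macrophage genes were lower too. The suppressive genes had a median log2 ratio of -0.46 (-0.52 to -0.35), below every one of 10000 random lists matched on expression (percentile 0.0). Ptgs2, the prostaglandin-forming cyclooxygenase, was 929.6 CPM in the KPC library and 174.8 CPM in the other, a ratio of 0.188 (0.172 to 0.206). Vegfa, an angiogenic growth factor, had a ratio of 0.188 (0.166 to 0.212). Retnla and Cd200r1 stood on the other side of this list, with ratios of 17.7 (15.7 to 20) and 3.81 (3.21 to 4.53). Of 2 further members, chosen after their values were seen, Arg1, which breaks down arginine, was 1040 and 401 CPM, a ratio of 0.386 (0.362 to 0.410), and Cd274, which encodes PD-L1, 144 and 102 CPM, a ratio of 0.709 (0.621 to 0.808).

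Different clusters held most of the macrophage/monocyte-like cells in each library. Cluster 8, led by Lyz2, Pf4 and Arg1 (median 6913 UMIs), held 764 KPC cells and 148 cells of the library labelled Ccr1-/-, and cluster 6, led by Apoe, C1qa and Mrc1 (median 1414.5 UMIs), held 201 and 893. Against the rest of its class, however, cluster 6 was led by the acinar genes Ctrb1, Try5 and Prss2. Its median mitochondrial share was 6.08%, against 1.74% in cluster 8. The split between these clusters can therefore be partly free RNA and cell quality. Within cluster 6 the median of the suppressive genes was 0.19, and within cluster 8 it was -0.27, both by CPM, the one scaling run within clusters. Arg1 had a ratio of 1.57 (1.11 to 2.31) within cluster 6 and 0.809 (0.752 to 0.868) within cluster 8. Signs of RNA quality moved with this class: all 10 of the mitochondrial transcripts and the nuclear transcripts Malat1 and Neat1 listed beforehand were higher in the library labelled Ccr1-/- (median log2 ratio 0.85 by CPM, 0.37 with TMM and 0.35 with median-of-ratios scaling), and the median mitochondrial share was 1.87% in KPC and 4.04% in the other. The median of all 9069 measured genes was itself 0.32, and TMM and median-of-ratios scaling shifted the log2 ratios of this class by -0.48 and -0.50 before the 10 CPM were added, and by less after it for low genes, so that genes with a ratio little above 1 changed side.

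Monocyte genes were lower for 14 of 16 members (median log2 ratio -1.29, -1.39 to -1.20; percentile 0.0), with medians of -1.15 within cluster 6 and -0.62 within cluster 8. Plac8 was 929.9 CPM in KPC and 50.3 CPM in the library labelled Ccr1-/-, a ratio of 0.0541 (0.0458 to 0.0636), and Ms4a4c had a ratio of 0.0351 (0.0167 to 0.0650), whereas F13a1 (1.57) and F10 (1.28) were higher by CPM, F10 not under the other scalings, F13a1 not within cluster 8 (0.9497) and F10 not within cluster 6 (0.926). Inflammatory cytokine genes were lower for 18 of 20 (median -0.98, -1.04 to -0.89; percentile 0.0), with a median of -0.70 within cluster 6 but -0.02 within cluster 8. The neutrophil-attracting chemokines Cxcl3 and Cxcl1 had ratios of 0.0137 (0.00890 to 0.0201) and 0.137 (0.116 to 0.160), and Cxcl1 was not lower within cluster 6 (1.37, 0.709 to 2.95). Tnf (1.06) and Il18 (1.05) lay near 1 by CPM for the class, but Tnf was lower within cluster 6 (0.447, 0.361 to 0.557) and higher within cluster 8 (2.09, 1.89 to 2.30). All 21 measured glycolysis and hypoxia genes were lower (median -1.17, -1.24 to -1.06; percentile 0.0; -0.85 within cluster 6 and -0.68 within cluster 8), from Ndrg1, with a ratio of 0.0852 (0.0535 to 0.129), and Vegfa to Pdk1 (0.610) and Pfkp (0.869). Interferon response genes were lower for 19 of 28 (median -0.75, -0.86 to -0.62; percentile 0.0), with medians of -0.28 within cluster 6 and -0.74 within cluster 8. Irf7, a regulator of interferon production, had a ratio of 0.0722 (0.0326 to 0.139) and Ifi205 0.161 (0.103 to 0.242), while the guanylate-binding protein genes Gbp5 and Gbp7 had ratios of 2.94 (2.16 to 4.01) and 2.32 (1.91 to 2.83), with Gbp5 at 0.740 (0.322 to 1.98) within cluster 6.

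The CCR1 ligand genes were lower for 4 of 7 (median log2 ratio -0.38, -0.47 to -0.30; percentile 26.0), a median that was 0.88 within cluster 6 and -0.16 within cluster 8. Ccl5 (0.354, 0.285 to 0.437) and Ccl7 (0.433, 0.386 to 0.485) were lower, and Ccl6 (1.39) and Ccl8 (1.39) were higher by CPM but not under either other scaling. Ccl8 went opposite ways by cluster, from 37.6 to 721 CPM in cluster 6 (19.2, 11.0 to 37.3) and from 2121 UMIs to 0 in cluster 8, while Ccl6 was higher in both (2.98 and 1.58). Within cluster 6 the intervals of Ccl5 (2.51, 0.935 to 9.50) and Ccl7 (0.945, 0.701 to 1.30) spanned 1. Of the MHC class II genes, which present antigen to CD4 T cells, 6 of 10 were lower (median -0.13, -0.17 to -0.06; percentile 40.0). The median was -0.61 with TMM, -0.63 with median-of-ratios scaling and -0.48 as the mean over cells, and -0.08 within cluster 6 and -0.02 within cluster 8 by CPM. Ratios of members ran from 0.618 for Ifi30 and 0.689 for H2-Ab1 to 1.06 for Ctss and 1.85 for Ciita, but within clusters 6 and 8 the ratios of Ciita were 0.744 (0.471 to 1.22) and 0.868 (0.489 to 1.45), those of Ctss 2.17 and 0.992, and those of Ifi30 1.13 and 0.695. MHC class I genes were lower for 10 of 16 (median -0.21, -0.34 to -0.13; percentile 1.30; 0.05 within cluster 6 and -0.39 within cluster 8), with the proteasome genes Psmb9 (0.352) and Psme1 (0.442) lowest and Nlrc5 (1.13) and H2-Q4 (1.26) highest. Within clusters 6 and 8 the ratios of H2-Q4 were 0.779 (0.512 to 1.23) and 0.807 (0.543 to 1.16), and those of Nlrc5 1.08 (0.611 to 2.04) and 0.745 (0.475 to 1.12). Arginine and polyamine metabolism genes were lower for 8 of 13 (median -0.38, -0.63 to -0.24; percentile 0.210), with medians of -0.49 within cluster 6 and -0.10 within cluster 8. The arginine transporter gene Slc7a2 had a ratio of 0.198 (0.168 to 0.233) and Odc1, which makes putrescine, 0.228 (0.203 to 0.256), against 1.76 for Sat1 and 1.96 for Srm. Within cluster 6 Srm was lower (0.508, 0.290 to 0.934), and Slc7a2 had 1 and 56 UMIs.

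Complement and lipid macrophage genes were higher for 15 of 25 (median log2 ratio 0.19, 0.13 to 0.25; percentile 95.1), a direction that flipped under TMM (-0.29) and median-of-ratios scaling (-0.30), and the median was 1.14 within cluster 6 and -0.23 within cluster 8. Selenop (3.91, 3.75 to 4.08) and the lipid droplet gene Plin2 (3.15, 2.97 to 3.34) were highest, and Spp1 (0.0602, 0.0541 to 0.0667) and Fabp5 (0.282, 0.263 to 0.302) lowest. Within cluster 8 Selenop was lower (0.739, 0.664 to 0.821), and within cluster 6 Fabp5 was higher (2.29, 1.70 to 3.15), whereas Plin2 was higher and Spp1 lower in both. Myeloid chemokine receptor genes were lower for 6 of 10 (median -0.13, -0.20 to 0.02; percentile 18.2), but the median was 0.15 within cluster 6 and 0.57 within cluster 8. Besides Ccr1, Cx3cr1 was lowest (0.459, 0.364 to 0.574), and C3ar1 (1.63) and Ccr5 (1.31, above 1 only by CPM) were highest. Ccr2, chosen after its values were seen, was 400.1 and 374 CPM (0.936, 0.871 to 1.00).

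Across all genes, the 10 lowest ratios in macrophage/monocyte-like cells of the library labelled Ccr1-/- belonged to Cxcl3, Serpinb2, Inhba, Plac8, Spp1, Prg4, Wfdc21, Ifitm1, Ms4a4c and Tnfrsf9, with log2 ratios from -5.10 to -2.95. Spp1, which encodes the secreted matrix protein osteopontin, was 2036 CPM in KPC and 122 CPM in the other library, and it was lower within cluster 6 (ratio 0.287, 0.220 to 0.377) and within cluster 8 (0.0994, 0.0863 to 0.114). The 10 highest belonged to Retnla, Tns1, P2rx7, Clec10a, Samd4, Ear2, Fkbp5, Abca6, Ifi202b and Tmcc1, with log2 ratios from 3.90 to 2.65. Retnla was 50.0 and 884 CPM, and it was higher within cluster 6 (2.77, 2.34 to 3.30) and within cluster 8 (6.01, 4.82 to 7.51). Clec10a, a lectin of macrophages and dendritic cells, was 33.6 and 401 CPM. Ifi202b had 1 UMI in KPC and 164 in the other library, a ratio of 332 (58.7 to 13173). P2rx7 and Clec10a are among the leading genes of cluster 6, but P2rx7 was higher within cluster 6 (12.2, 7.49 to 21.4) and within cluster 8 (5.14, 4.19 to 6.30), as was Clec10a (9.12, 5.88 to 14.99, and 1.55, 1.11 to 2.14).

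**Figure D3:**
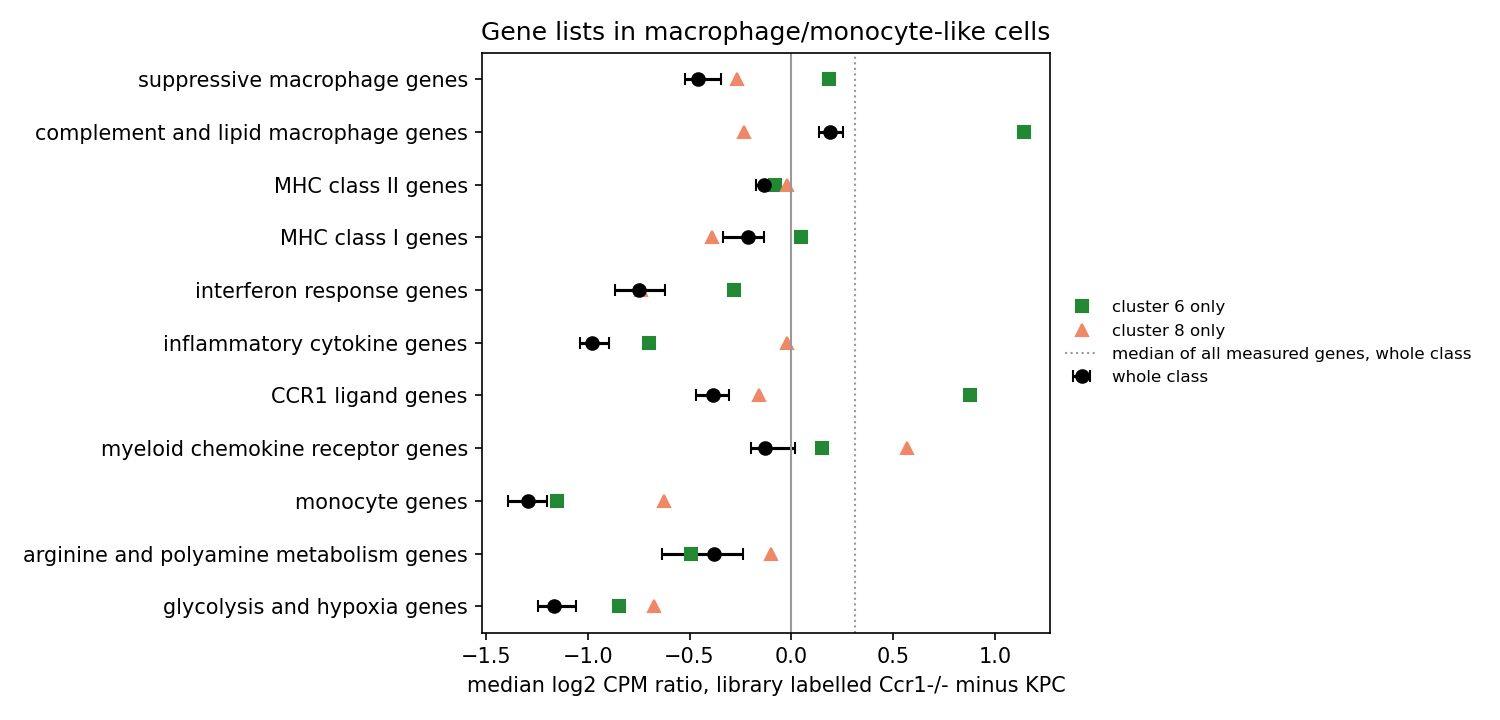
Median log2 ratio of each gene list in macrophage/monocyte-like cells (library labelled Ccr1-/- minus KPC, log2 CPM with 10 CPM added) for the whole class (black points, 95% intervals from Poisson redraws), cluster 6 (green squares) and cluster 8 (orange triangles), with the median of all measured genes as a dotted line at 0.32. Glycolysis and hypoxia genes lie at -1.17 in the whole class, and the suppressive genes at -0.46 in the whole class, 0.19 in cluster 6 and -0.27 in cluster 8.

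Neutrophil-like cells also carry Ccr1 and were compared for activation and maturity. Ltf (lactoferrin) was 866 and 103 CPM, a ratio of 0.119 (0.0907 to 0.154), and Camp (cathelicidin) 3443 and 704 CPM, a ratio of 0.205 (0.185 to 0.226). Within cluster 9, which held 608 and 287 of the cells, their ratios were 0.722 (0.424 to 1.18) and 0.393 (0.0751 to 1.32), intervals that both span 1. Of the 16 maturity genes 10 were lower (median log2 ratio -0.50, -0.63 to -0.30; percentile 0.0100), with Retnlg (2.22, 2.12 to 2.32) and the chemokine receptor gene Cxcr2 (1.84, 1.57 to 2.16) highest. The list pools granule protein genes such as Ltf and Camp with genes such as Retnlg and Cxcr2, which went opposite ways. Its median therefore does not say whether the cells were more or less mature. Activation genes were lower for 10 of 16 (median -0.10, -0.22 to -0.03; percentile 23.1), from Cxcl3 (0.433, 0.383 to 0.488) and Acod1 (0.593, 0.550 to 0.638) to Nfkbia (1.28) and Arg2 (1.56). With TMM and median-of-ratios scaling the activation median was -0.34 and -0.35 and the maturity median -0.74 and -0.75. The lowest ratios across all genes were those of Ltf, H2ac24, Areg, Lst1 and Camp, and the highest those of Bcl2l15, Gdpd3, Rab15 (1 and 33 UMIs; 98.6, 16.5 to 4013), Chil3 (407.8 and 2177 CPM) and the immediate early gene Fos (4.46, 4.11 to 4.86). Within cluster 9 the maturity median was 0.41 and the activation median -0.22 by CPM, and Chil3 had a ratio of 35.9 (28.4 to 46.0). The small cluster 26, led by Ngp and Camp, held 32 and 7 cells.

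T/NK-like cells were compared for signs of cytotoxic and exhausted states. Naive and memory genes and cytotoxicity genes were lower in the library labelled Ccr1-/-, and exhaustion and regulatory T cell genes were higher. Cytotoxicity genes were lower for 11 of 18 (median log2 ratio -0.39, -0.55 to -0.24; percentile 0.0). Cd8b1, a chain of the CD8 coreceptor, was 231 and 55.1 CPM (0.239, 0.206 to 0.276) and Gzma 63.3 and 11.96 CPM (0.189, 0.136 to 0.256), whereas Gzmk (2.11, 1.76 to 2.52) and Ccl4 (2.04, 1.90 to 2.18) were higher. Exhaustion genes were higher for 10 of 12 (median 0.68, 0.58 to 0.76; percentile 99.9), with the checkpoint receptor gene Pdcd1 at 29.3 and 127 CPM (4.34, 3.83 to 4.93) and Entpd1 at 4.31 (3.50 to 5.30), against Lag3 at 0.419 (0.288 to 0.592) and Rgs16 at 0.985. Regulatory T cell genes were higher for 14 of 15 (median 0.64, 0.49 to 0.69; percentile 99.9), with Il2ra (3.08, 2.78 to 3.41) and Gata3 (2.35, 2.18 to 2.53) highest and Il10 (0.785) and Capg (1.01) lowest. Naive and memory genes were lower for 10 of 11 (median -0.99, -1.07 to -0.91; percentile 0.0), with Dapl1 (0.113, 0.0855 to 0.146) and Igfbp4 (0.134, 0.106 to 0.167) lowest, Bach2 at 0.768, and Il7r at 2.41 (2.32 to 2.50).

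The T/NK-like cells came from different clusters in each library. Clusters 3 and 7, led by Lef1, held 1095 and 994 KPC cells and 103 and 91 cells of the library labelled Ccr1-/-, and cluster 16, led by Calca and Pard3, held 47 and 201. Cluster 19, named NK-like and led by Gzma, held 183 KPC cells and 15 of the library labelled Ccr1-/-. In cluster 4 Gzma had a ratio of 1.26 (0.562 to 2.56), but in cluster 2 it had 55 and 0 UMIs, with an upper bound of 0.253. Within cluster 4, named CD8 T-like and holding 844 and 349 cells, the cytotoxicity median was 0.01 (against -0.81 to -0.11 in clusters 2, 3, 7, 11 and 16), the exhaustion median 1.28, the regulatory median 1.02 and the naive and memory median -1.06, and Pdcd1 was 16.3 and 60.4 CPM (3.71, 2.55 to 5.37). That name rests on Ccl5, Nkg7, Eomes and Gzmk, and Cd8b1 was lower within cluster 4 (340.7 and 109.3 CPM; 0.321, 0.258 to 0.395). Its cells may therefore differ in kind between the libraries, and these medians can reflect that. The naive and memory median was -0.66 in cluster 2, -0.12 and 0.10 in the Lef1-led clusters 3 and 7, -0.25 in cluster 11 and -0.42 in cluster 16, and Bach2 was higher in clusters 3 (1.23, 1.13 to 1.35), 7 (1.62) and 16 (1.61). Within cluster 2, named regulatory T-like, the regulatory median was 0.04 and the exhaustion median -0.17, in cluster 11 they were -0.30 and -0.16, and in cluster 16 -0.73 and 0.71, with Gata3 lower there (0.701, 0.594 to 0.830). Il10 and Rgs16 were lower in cluster 2 (0.274 and 0.338) and higher in cluster 4 (4.89 and 2.54). Il2ra had a ratio of 1.03 (0.850 to 1.24) in cluster 2 and 3.25 (1.96 to 5.30) in cluster 4. Gata3 had ratios of 1.19 (1.055 to 1.33) and 1.36 (1.04 to 1.77) in that order. Across all genes Ly6c2, Dapl1, Cd8b1, Ms4a4c and Gzma had the lowest ratios and Gdpd3, Calca, Pard3, Pde7b and Frmd5 the highest, with Calca, Pard3 and Pde7b being leading genes of cluster 16. The median of all 8953 measured genes was 0.27, and TMM and median-of-ratios scaling shifted the log2 ratios of the class by -0.42 and -0.41 before the 10 CPM were added, which turned none of the 4 T cell list medians. The exhaustion median was then 0.33 and 0.34 and the regulatory median 0.24 and 0.25, and Capg (1.01) lay below 1.

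B/plasma-like cells numbered 3830 and 570, with 3348 and 463 in cluster 0, led by Bank1, and 281 and 83 in cluster 12, led by Ighg2b and Igha. Fcer2a (CD23) was 203 and 43.8 CPM (0.216, 0.173 to 0.266), and Cr2 (the complement receptor CD21) 203 and 54.8 CPM (0.270, 0.222 to 0.325), with Fam43a, Ly6k and Slc15a2 also among the 5 lowest. Within cluster 0 the ratios of Fcer2a and Cr2 were 0.288 (0.230 to 0.357) and 0.382 (0.314 to 0.462). Gdpd3 (165, 95.2 to 314), Dnm3, Serinc5, Camk2b and Znrf3 had the highest ratios, with Dnm3 at 6.10 (4.798 to 7.79) within cluster 12 and at 34 and 0 UMIs in cluster 0. In dendritic-like cells (348 and 262 cells) Apol7c, Cox6a2, Siglech, Grm8 and Ly6c2 were lowest. Siglech and Cox6a2, genes of plasmacytoid dendritic cells, were 235 and 7.29 CPM and 147 and 0.810 CPM, and both lead cluster 25, which held 52 and 3 cells. Apol7c leads cluster 17, which held 141 and 68 cells, and within it Apol7c was 802 and 67.3 CPM (0.0839, 0.0445 to 0.144). Fkbp5 (10.04, 7.62 to 13.4), Ear2 (10.9, 7.48 to 16.3), Ifi202b (0 and 65 UMIs), Tnip3 (6.80) and the CCR1 ligand gene Ccl9 (6.85, 5.59 to 8.45) were highest.

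Fibroblast-like cells of the library labelled Ccr1-/- had lower levels of contractile, inflammatory and matrix genes. Myofibroblast genes were lower for 15 of 18 (median log2 ratio -1.66, -1.71 to -1.62; percentile 0.0), with smooth muscle actin (Acta2) at 524.7 and 56.2 CPM (0.107, 0.0984 to 0.116) and Tnc at 0.0924 (0.0855 to 0.0996), and with Postn (1.43) and Mmp11 (4.30, 3.73 to 4.98) higher by CPM. Inflammatory fibroblast genes were lower for 15 of 20 (median -1.45, -1.49 to -1.40; percentile 0.0), with Saa3 at 1936 and 131 CPM (0.0675, 0.0639 to 0.0712) and Ccl2 at 0.108 (0.102 to 0.115), and with Dpp4 (5.80, 5.26 to 6.42) and Clec3b (3.57, 3.45 to 3.70) higher. Antigen presenting fibroblast genes were lower for 8 of 9 (median -1.29, -1.44 to -1.21; percentile 0.0), among them Slpi (0.143), H2-Aa (0.294) and H2-Ab1 (0.309). The B/plasma gene Igkc moved the same way in fibroblast-like cells, at 2939 and 594 CPM. Scaling on acinar and B/plasma markers estimated free RNA at 17.6% of their UMIs in KPC and 12.3% in the other library. Free RNA alone would give all classes a like level. In KPC, however, Igkc was 239.9 CPM in macrophage/monocyte-like, 516 in T/NK-like, 2484 in neutrophil-like and 6436 in dendritic-like cells. The estimate can therefore include B/plasma RNA from doublets left after the calls. Neither source was subtracted for this list, so either may add to this difference. Collagen and matrix genes were lower for 19 of 22 (median -0.89, -0.91 to -0.86; percentile 0.120), with Timp1 (0.129) and Col6a3 (0.184) lowest and Dcn (2.16) and Mmp2 (1.49) highest.

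Nearly separate clusters made up the fibroblast-like cells: cluster 5, led by Col1a1 and Timp1, held 1077 KPC cells and 97 of the library labelled Ccr1-/-, and cluster 1, led by Apod and Inmt, held 49 and 2617. Within cluster 5 the medians by CPM were 0.04 for the myofibroblast, 0.19 for the collagen, -0.67 for the inflammatory and -1.57 for the antigen presenting genes, and within cluster 1 they were -0.16, -0.57, -0.11 and -1.25 in that order. Within cluster 5 the ratio of Acta2 was 0.984 (0.902 to 1.07), that of Tnc 0.822, that of Timp1 0.880 and that of Saa3 0.360, and Clec3b (0.629) and Dcn (0.938) were lower there. Within cluster 1 Ccl2 had 1 and 755 UMIs and Saa3 a ratio of 1.37 (0.661 to 3.42). Inmt, Apod, Galnt15, Fmo2 and Acss3 had the highest ratios across all genes, and the first 4 of these lead cluster 1. All 5 were also higher within cluster 1, from 6.77 (4.28 to 11.4) for Fmo2 to 49.1 (8.81 to 1941) for Acss3 with 1 KPC UMI, and within cluster 5, from 2.42 (1.43 to 3.89) for Acss3 to 15.5 (11.0 to 21.9) for Inmt. Saa3, Serpinb2 (2086 and 0 UMIs), Tnc, Cxcl5 and Ereg had the lowest.

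Epithelial-like cells were compared for tumour cell programmes, though which of them were malignant was not tested. In the library labelled Ccr1-/-, classical and basal tumour genes and chemokine genes were lower, and mesenchymal and MHC class I genes were higher. Classical genes were lower for 17 of 22 (median log2 ratio -0.51, -0.61 to -0.45; percentile 0.0), with Agr2 (0.199, 0.182 to 0.216) and Anxa10 (0.220, 0.207 to 0.235) lowest and Lypd8 (3.05) and Foxa2 (2.06) highest. Basal genes were lower for 7 of 9 (median -0.77, -0.90 to -0.63; percentile 0.0200), with Ly6d at 734 and 70.8 CPM (0.0964, 0.0891 to 0.104) and Areg at 0.317 (0.294 to 0.342), against 0.943 for Lamb3 and 1.12 for Lamc2. Genes on the tumour cell chemokine list were lower for 11 of 12 (median -0.92, -1.03 to -0.80; percentile 0.0). Cxcl5, which attracts neutrophils, was 215 and 18.6 CPM (0.0866, 0.0741 to 0.101). The cytokine gene Il33, also on that list, was 93.7 and 6.18 CPM (0.0659, 0.0500 to 0.0855), with Cxcl1 at 0.535 and Cxcl17 at 0.811. Mesenchymal genes were higher for 6 of 9 (median 0.77, 0.59 to 0.90; percentile 99.4), with vimentin (Vim) at 24.8 and 211 CPM (8.51, 7.55 to 9.61) and Cdh2 at 18.6 (10.8 to 34.6), against S100a4 (0.816) and Fn1 (0.861). MHC class I genes were higher for 10 of 11 (median 0.54, 0.48 to 0.67; percentile 97.4), with H2-Q6 (4.17, 3.22 to 5.45) and H2-Q4 (3.44, 2.75 to 4.34) highest and H2-T23 (0.903) and Tapbp (1.10) lowest. TMM and median-of-ratios scaling shifted the log2 ratios of this class by -0.41 and -0.38 before the 10 CPM were added, with which the MHC class I median was 0.27 and 0.28, the mesenchymal median 0.57 and 0.58, and Tapbp and Lamc2 lay below 1.

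The epithelial-like class joined 2 clusters. Cluster 10, led by Tff1 and Gkn1, held 414 KPC cells and 379 of the library labelled Ccr1-/-, and cluster 20, led by Pkhd1 and other genes of duct cells, held 0 and 197. Cluster 20 also held hormone UMIs at 21097 CPM for Ins2, 11264 CPM for Ins1 and 2188 CPM for Gcg, and Ins2, Ins1, Iapp and Gcg had, with Chil4, the highest ratios across all genes. In cluster 10 Ins2 was 0.947 and 3.49 CPM, Ins1 2.68 and 1.21 CPM, and Chil4 0.789 and 1175 CPM. Within cluster 10 the list medians by CPM were classical -0.31, basal -0.44, chemokine -0.93, mesenchymal 0.78 and MHC class I 0.48. Vim had a ratio of 11.0 (9.76 to 12.4) there and Anxa10 0.287 (0.270 to 0.306), while Lamb3 (1.22, 1.11 to 1.34) and Fn1 (1.11, 1.06 to 1.17) lay above 1 there by CPM, the one scaling run within clusters. Mucl3, Ly6d, Fabp5, Cxcl5 and Ctla2a had the lowest ratios across all genes.

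Endothelial-like cells were few (57 and 145), and their mix differed: 44 and 90 were in cluster 21, led by Egfl7, and 13 and 55 in cluster 24, led by Ccl21a and Lyve1, genes of lymphatic vessels. List values within these clusters were not computed. Angiogenic genes were lower in the library labelled Ccr1-/- for 12 of 15 (median log2 ratio -0.68, -0.81 to -0.54; percentile 0.0100), and adhesion genes for 7 of 11 (median -0.10, -0.36 to 0.14; percentile 20.9).

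Lists that apply to every class were also compared in the 7 classes with at least 200 cells in each library. Their values within clusters were not computed, so differences in cluster mix can enter them. Of the 576 epithelial-like cells of the library labelled Ccr1-/-, for example, 197 were in cluster 20, which held 0 KPC cells. Proliferation genes were lower for all 16 measured members in epithelial-like cells (median log2 ratio -0.79, -0.82 to -0.69), for 8 of 11 in macrophage/monocyte-like cells (-0.72) and for 13 of 14 in dendritic-like cells (-0.55). Their medians in the other classes were -0.27 in neutrophil-like, -0.11 in B/plasma-like, 0.04 in T/NK-like and 0.15 in fibroblast-like cells, and the last pair turned negative under both other scalings. By CPM dissociation stress genes were higher in neutrophil-like (0.58; 0.33 with TMM and 0.32 with median-of-ratios scaling), dendritic-like (0.47; 0.20 and 0.22), T/NK-like (0.37; 0.02 and 0.03) and fibroblast-like cells (0.15, turning to -0.26 and -0.30) and lower in B/plasma-like (-0.62), epithelial-like (-0.22) and macrophage/monocyte-like cells (-0.20). RNA quality genes had medians by CPM and with TMM of 0.73 and 0.45 in dendritic-like, 0.57 and 0.16 in fibroblast-like, 0.36 and 0.11 in neutrophil-like, 0.32 and 0.13 in B/plasma-like, 0.05 and -0.37 in T/NK-like and -0.01 and -0.41 in epithelial-like cells. Median-of-ratios scaling gave 0.47, 0.12, 0.10, 0.12, -0.36 and -0.39 in that order.

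Acinar genes, listed as markers of free RNA, were higher in the library labelled Ccr1-/- for all 12 members in each of the 7 classes, with medians from 4.25 in B/plasma-like to 6.49 in neutrophil-like cells and 5.09 in macrophage/monocyte-like cells. Of the genes listed for sex, Xist, which silences an X chromosome, passed the expression minimum in every class and was lower, with log2 ratios from -3.26 in B/plasma-like to -1.94 in fibroblast-like cells. The Y-linked Ddx3y passed it only in neutrophil-like cells, where the median of both was -0.87. Over all kept cells it had 120 and 188 UMIs, 1.50 and 4.73 CPM, a ratio of 3.16 (2.50 to 4.001), and Eif2s3y, Kdm5d and Uty had 0 to 5 UMIs each in either library. Cells with an Xist UMI were 79.3% (78.5 to 80.0) of the KPC library and 8.97% (8.34 to 9.64) of the library labelled Ccr1-/-.

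**Figure D4:**
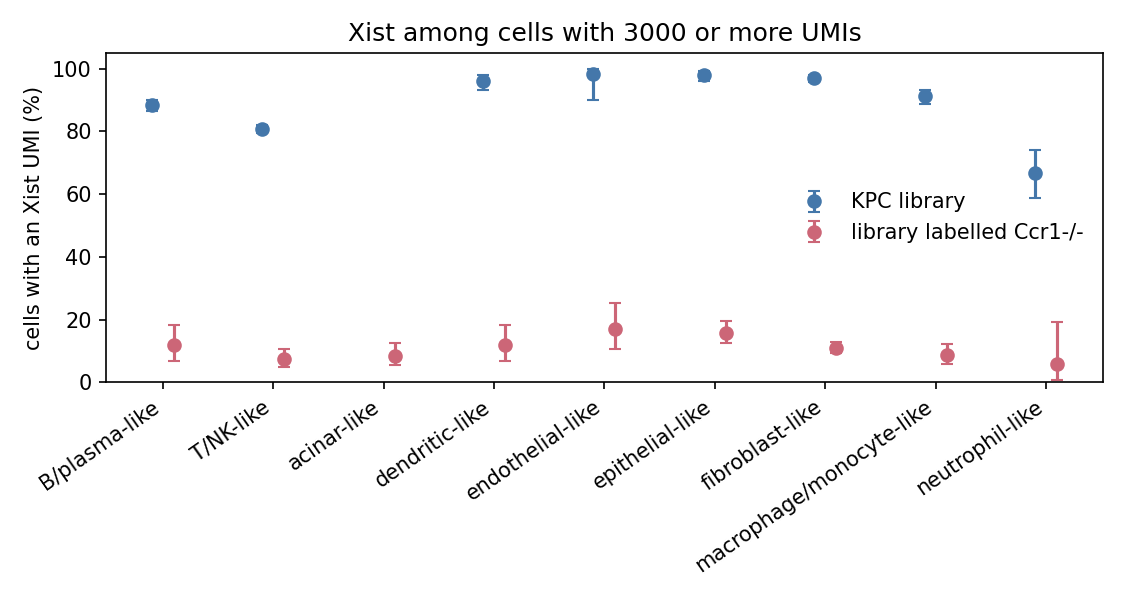
Share of cells with at least 1 Xist UMI (percent) among cells with 3000 or more UMIs, by cell class, in the KPC library (blue) and the library labelled Ccr1-/- (red), with exact 95% binomial intervals. Over all classes the shares were 87.2% and 11.0%.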

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

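Differences are the library labelled Ccr1-/- minus KPC, in percentage points for shares and log2 for levels. There were 115 values under alternatives, all for the shares and levels named in the next paragraphs. Medians of other lists were not counted. Under TMM and median-of-ratios scaling, those of complement and lipid macrophage genes and of proliferation genes in T/NK- and fibroblast-like cells turned. So did those of dissociation stress genes in fibroblast-like and RNA quality genes in T/NK-like cells. Of the counted values under alternatives fixed at the outset, 56 stayed within the counting interval of the reported value. Another 32 moved beyond it with the same sign, some nearer to no difference, and 0 turned. Of those under alternatives chosen after seeing the data, 9 stayed, 13 moved and 5 turned. The cause was not tested for any of them. Leaving out a replicate was not run, with 1 library with a matrix per genotype, and the alternative without a minimum for members has no value for the single gene Ccr1. No paired analysis was possible because the genotypes share 1 replicate number with a matrix. Depth limits classes of few cells and genes of few UMIs, and no alternative touches the variation between mice.

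The reported differences in share were 5.95 points for macrophage/monocyte-like, -1.33 for neutrophil-like, -19.3 for T/NK-like, 4.28 for epithelial-like and 26.9 for fibroblast-like cells. With 500 genes and 10% mitochondrial UMIs the macrophage/monocyte-like difference was 4.21. With classes from each cell's own markers it was 3.93, T/NK-like -22.0 and fibroblast-like 19.6. With no cell filter the epithelial-like difference was 1.59 and the fibroblast-like 24.1. At resolution 0.5 the epithelial-like difference was 5.19, and at resolution 2 also 5.19. With each library clustered on its own, epithelial-like was 1.61 and fibroblast-like 15.9, and 1042 cells of the library labelled Ccr1-/- were unnamed. Without T/NK- and B/plasma-like cells in the denominator, macrophage/monocyte-like (-6.71) and epithelial-like (-0.557) turned, and neutrophil-like was -11.6 and fibroblast-like 19.1. Without clusters 0, 3 and 7 and acinar-like cells, macrophage/monocyte-like was 1.64, neutrophil-like -4.96, epithelial-like 2.68 and fibroblast-like 24.8. Cluster 10 alone gave an epithelial-like difference of 1.65.

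For levels, TMM scaling gave -1.42 for Ccr1 in macrophage/monocyte-like cells (reported -0.98), -0.90 for suppressive, -0.61 for MHC class II, -1.07 for interferon response, -0.86 for CCR1 ligand and -0.67 for cytotoxicity genes, and median-of-ratios scaling gave -1.44, -0.92, -0.63, -1.08, -0.88 and -0.66 in that order. The mean over cells gave -1.32 for Ccr1, -0.61 for suppressive and -0.48 for MHC class II genes. Thinned cells gave -0.54 for suppressive and -0.32 for MHC class II genes, and separate clustering -0.18 for MHC class II genes. Adding 1 CPM gave -1.09 for interferon response genes, and no minimum for members -0.44. Subtracting free RNA gave -0.0131 for MHC class II and -0.25 for CCR1 ligand genes. In cluster 6 alone, Ccr1 was -1.20 and interferon response genes -0.28, and suppressive (0.19) and CCR1 ligand genes (0.88) turned. In cluster 8 alone, Ccr1 was -0.68, suppressive genes -0.27, MHC class II genes -0.0207 and CCR1 ligand genes -0.16. Cytotoxicity genes turned in cluster 4 (0.0071).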

Other observations

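The tests on Ccr1 and Xist below were chosen after their results were seen. Of those on Arg1, thinning, subtraction of free RNA and the ratio within cluster 8 were chosen before, and the value within cluster 6 after. The genes and clusters of the next paragraph were also chosen after their values were seen.

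Some genes differed in every class compared. In each of 7 classes, 24 genes of the acinar marker list and 10 genes outside it were at least 2-fold higher in the library labelled Ccr1-/- on the log2 scale with 10 CPM added, and 3 were at least 2-fold lower. The 10 were Gdpd3, Fkbp5, Ccnd3, Plxdc2, Hmgcs2, S100pbp, Prss3b, Gm2000, Gm2663 and Gm8797, with log2 ratios from 1.56 to 4.36 for Gdpd3 and from 1.03 to 2.91 for Fkbp5, a target gene of the glucocorticoid receptor. Of these 10, Prss3b, Gm2663 and Hmgcs2 were higher in acinar-like cells, at 16668, 2427 and 1199 CPM in cluster 14 and 238, 28.3 and 172 CPM in all other cells of that library, while the other 7 were lower in cluster 14 than in the other cells. The 3 were Xist, Col3a1 and Ighm. Cluster 23, left unnamed, held 0 KPC cells and 78 of the library labelled Ccr1-/- and was led by Cfd, Scd1 and Fabp4, genes of fat cells, and cluster 27, also unnamed, held 1 and 38 and was led by Dclk1, with Rgs13 and Sh2d6 among its leading genes.

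Arg1 was lower in macrophage/monocyte-like cells of the library labelled Ccr1-/- (1040 and 401 CPM). With every cell thinned to 1 depth the ratio was 0.209 (0.174 to 0.249). Thinning leaves each cell's expected CPM unchanged, so this cannot decide whether shallower cells account for it. Free RNA as estimated here does not account for it, since after subtraction of its profile the ratio was 0.424 (0.398 to 0.451). Within cluster 8, which holds most of the Arg1 UMIs, the ratio was 0.809 (0.752 to 0.868), across the bound of 0.8 set beforehand, so that test gave no verdict. Within cluster 6, with 893 of the 1041 cells of that library, Arg1 was higher (106.4 and 167.6 CPM; 1.57, 1.11 to 2.31). With these clusters, lower Arg1 within them alone could not give the class ratio of 0.386. But Arg1 is a leading gene of cluster 8 and was not kept out of the genes open to clustering. A difference in Arg1 can therefore itself change the cluster mix, and these values cannot separate the mix from the level of Arg1. An effect of the genotype, on the mix or within cluster 8, stays open, with mouse and run the same split.

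Ccr1 UMIs remained in the library labelled Ccr1-/-. Free RNA would give all types a like level, but neutrophil-like cells held 207 times (69.7 to 1015) the CPM of B/plasma-like cells there. The UMIs were not limited to the minority of cells with Xist, since macrophage/monocyte- and neutrophil-like cells without an Xist UMI held 76.9 times (26.1 to 375) the B/plasma-like level. A transcript kept outside the deleted part could give the 489 UMIs (447 to 534), and this cannot be told apart from an intact gene or a wrong label, because the count tables hold no read positions.

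Xist was found in a minority of cells of the library labelled Ccr1-/-. Low depth does not account for it, since among cells with 3000 or more UMIs 11.0% (10.0002 to 12.1) had Xist, against 87.2% in KPC, and free RNA spread by depth would put it in 50.4% of those cells (observed over expected 0.219, 0.198 to 0.240). Single cells of the KPC library mixed in would leave acinar-like cells, of which KPC has 0, with no more Xist than free RNA gives, but 5.65% (3.32 to 8.89) of them had 3 or more Xist UMIs, against 0.0814% expected if all 30 acinar-like cells with Xist had it from free RNA. Male cells would bring Y-linked genes, but Ddx3y, Eif2s3y, Kdm5d and Uty summed to 4.85 CPM (4.19 to 5.59), nearly all of it Ddx3y, which was no higher in cells without Xist than in cells with it (0.926, 0.606 to 1.47). Over all kept cells Ddx3y was nonetheless above the KPC library (1.50 CPM in KPC and 4.73 CPM in the other). Cells of another animal may give the minority with Xist, but not by themselves a majority with neither Xist nor more Ddx3y than that minority. Loss of an X chromosome may give such a majority, and neither was tested.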
